A study of Homo sapiens with 6 samples.

How the data were processed

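The series holds 6 RNA-seq samples of transgenic human embryonic kidney cells, 3 with and 3 without NAEK for 48 h. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and polyA RNA was selected and fragmented before library preparation. Reads were aligned with TopHat2 to GRCh38, per the submitters' processing notes, which give no version and no order of steps. The counting program, the gene annotation and the strand setting are not given in the sources used here. Without a strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Reads of near-identical copies, as in the histone, actin, tubulin, ribosomal protein, metallothionein and TRIM families, may have been split between members.

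The deposited table gives 1 value per gene and sample for 60107 Ensembl gene identifiers. From the values, the unit is RPKM as deposited by the authors: reads scaled by gene length in kilobases and by the sample total. The file does not say whether single reads or pairs were counted, and in the second case the values are FPKM. All 6 value columns belong to the 6 samples. Of 34749 genes above 0 in any sample, 34746 (99.99%) had values that were whole numbers of reads for 1 whole-number gene length. Lengths up to 60000 bases were searched, with a tolerance of 0.0002 of a read, wider only at the largest read numbers. A gene above 0 in only 1 sample can fit some length by accident. The recovered totals per sample were 19627996, 19479886 and 20687566 reads without NAEK and 20965739, 19415436 and 18562269 with it, and the recovered reads summed to 99.68% to 99.69% of them. A recovered read number is the smallest that fits. Mitochondrial genes took 2.92% to 3.25% of the reads and the 10 most abundant genes 4.93% to 5.58%. An RPKM floor of 3 reads in a gene of 1 kb lay between 0.143 and 0.162. Such a floor covers counting error only.

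The plan made before the data were examined named 1 test for counts and another for normalized values. Since the values are RPKM, the second applied. Genes with at least 1 RPKM in at least 3 of the 6 samples were kept, and log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, robust moderation and the group as the only term. Fold changes are with minus without NAEK on that scale, which understates changes of low genes; folds in the text are ratios of mean RPKM. P-values are two-sided and adjusted by Benjamini and Hochberg over the 15540 tested genes. Names and coordinates come from GENCODE 29 on GRCh38, which named 56531 of the identifiers and 15318 of those tested, and left 222 tested identifiers without a name.

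The 28 gene lists were fixed before the data were examined. The 26 with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, with an estimated correlation and the rotation test fry as alternatives. Camera compares a list with the other genes, and fry compares it with no change. With an estimated correlation camera also takes its degrees of freedom from the 6 samples, which makes it stricter. The result of 1 of the other lists is not reported here. The annotated stop codon of every coding transcript gave the TAG class, with transcripts annotated for nonsense-mediated decay counted among them. The named genes were also set beforehand. They are the 12 with the largest log2 fold change in each direction among genes past adjusted p 0.05 whose groups do not overlap and whose mean is at least 5 RPKM, up to 4 members of smallest p of each list, and ASNS, DDIT3, HSPA5, ETF1, UPF1 and SLC7A5. HSPA1A, HSPB1, AHSA1, MT-CO1 and MT-ATP6 were added after the results had been seen, as was the choice of which list members to print. No Y-linked gene or XIST was to be named.

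The tests were also tested on simulated data, after they had been run on the real values. Reads were drawn for the real genes from the real means and library sizes, with some genes changed by known folds. With a coefficient of variation of 2% beyond counting, limma on 15530 simulated genes recovered 57 of 61 genes changed 2-fold, 55 of 65 changed 1.5-fold and 32 of 67 changed 1.25-fold, and 7.45% of its calls were unchanged genes. With 10%, on 15491 genes, it recovered 58 of 62, 39 of 67 and 4 of 64, and 8.93% of its calls were unchanged genes. Both shares of unchanged genes lie above the threshold of 0.05. In the first simulation 15297 of the 15530 genes were unchanged, whereas 5746 of the real genes passed. Recovery and such shares depend on how many genes change, so they do not carry over to the real calls. Camera called the 1 list shifted 1.1-fold and 0 of 25 unchanged lists in each simulation, whose genes vary independently.

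Alternatives planned beforehand were other scalings, other filters on low values, a smaller pseudocount of 0.1, plain limma, a block for the replicate number, stricter thresholds and leaving out each sample. Added after seeing the data were limma-voom on the recovered reads and the removal of each sample's trend on GC content and transcript length, alone or with the block. Lists of SRF, YAP, ERK and DUX4 target genes were also drawn up after values had been seen, and are used only in the closing section. The criteria for the DUX4 list and for reads shared between paralogs were narrowed after their first results were seen, to leave out the 3 gene families that had prompted the list and, for shared reads, to count only families with a member past adjusted p 0.05. Figures were drawn with matplotlib 3.10.9, and tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.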

Results

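PolyA-selected RNA from transgenic human embryonic kidney cells was sequenced after 48 h with or without NAEK, with 3 samples in each group, all at passage 10. The labels do not spell out NAEK or the transgene. In genetic code expansion work the name stands for a lysine analogue that is inserted into proteins at amber (TAG) stop codons. The stated aim was to compare mRNA abundance between the 2 conditions. All 6 samples are of transgenic cells, so an effect of NAEK itself cannot be told apart from one that needs the transgene. The samples held between 18562269 and 20965739 reads, as recovered from the deposited RPKM values, and 1 read in a gene of 1 kb was worth 0.0477 to 0.0539 RPKM. Between 26896 and 27468 genes were above 0 in each sample. The labels do not say that the samples of a group came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

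By the rule for naming genes, the largest rises with NAEK were those of H3.Y, TAGLN, KRT17, ACTN2 and ACTA2, and the largest falls those of INSIG1, ENSG00000263463 and SREBF1. TAGLN, an actin-binding protein of smooth muscle, rose from 2.44 ± 0.208 to 17.5 ± 1.84 RPKM (SD, n = 3), 7.15-fold. INSIG1, which holds back the sterol-regulated transcription factors in the endoplasmic reticulum, fell from 103 ± 2.46 to 30.7 ± 1.70 RPKM (SD, n = 3), 3.35-fold lower. Of 15540 genes tested with limma, 5746 passed an adjusted p of 0.05, of which 2870 were higher and 2876 lower with NAEK. Most changes were small: the median absolute log2 fold change of these genes was 0.24. It was at least 1, on log2(RPKM + 1), for 30 higher and 26 lower genes. That scale understates changes of low genes, so further genes pass 2-fold by the ratio of mean RPKM. COL12A1 (2.13-fold) and SPRY4 (3.04-fold) are such genes, at log2 fold changes of 0.98 and 0.93. All 3 samples with NAEK lay on one side of all 3 samples without it for 7768 genes, 50% of those tested, against 10% by chance.

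**Figure D1:**
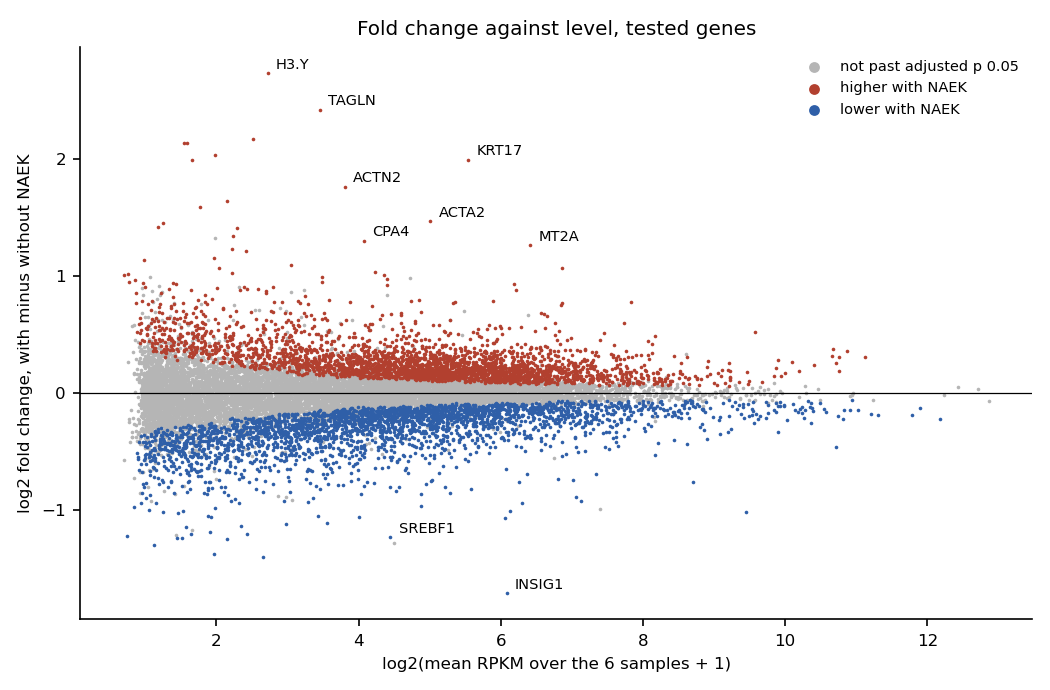
Log2 fold change (with minus without NAEK, on log2(RPKM + 1)) against log2 of the mean RPKM plus 1 over the 6 samples, 1 point per tested gene, with H3.Y and TAGLN highest and INSIG1 lowest. Red points are the 2870 genes higher and blue points the 2876 genes lower at limma adjusted p 0.05, grey points the others.

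Among the 12 genes with the largest rise were 3 of the actin cytoskeleton besides the keratin gene KRT17. TAGLN (ENSG00000149591; GRCh38 chromosome 11, 117199321 to 117204782) had a log2 fold change of 2.42 ± 0.08 (SE; limma adjusted p = 2.11e-07). KRT17, an intermediate filament gene of basal epithelia (ENSG00000128422; chromosome 17, 41619441 to 41624842), rose 4.14-fold to 73.4 ± 0.613 RPKM (SD, n = 3). ACTN2, a muscle alpha-actinin, rose 3.82-fold to 20.6 ± 0.408 RPKM, and ACTA2, smooth muscle actin, rose 2.87-fold from 16.1 ± 1.15 RPKM (SD, n = 3). On the opposite strand PCSK7, at a mean of 32.8 RPKM, shares 446 exon bases with TAGLN. ACTA2-AS1 (1.29 RPKM) and FAS (23.1 RPKM) share 516 and 380 with ACTA2, and the strand setting of the counts is not given in the sources used here. H3.Y, a histone H3 variant gene (ENSG00000269466, chromosome 5, 17654870 to 17655847), had the largest fold, 13.4, from a mean of 6.33 to 83.7 reads per sample. The fold was 21.7 without the first sample without NAEK and 10.03 without the second. Histone genes resemble one another, so the gene that its reads came from is uncertain.

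The other genes with the largest rise came from several classes. They were the carboxypeptidase gene CPA4 (2.63-fold), the metallothionein gene MT2A (2.42-fold), the ETS transcription factor gene ETV5 (2.38-fold) and the cytokine gene IL32 (2.13-fold). COL12A1, a collagen gene, rose 2.13-fold, TNFRSF12A, the receptor of the cytokine TWEAK, 2.10-fold, and FOSL1, a subunit of the transcription factor AP-1, 2.09-fold. Their limma adjusted p lay between 6.998e-08 for MT2A and 1.62e-05 for FOSL1.

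The genes with the largest fall included 3 of lipid synthesis. INSIG1 (ENSG00000186480; chromosome 7, 155297776 to 155310235) had a log2 fold change of -1.71 ± 0.04 (SE; limma adjusted p = 1.78e-08). SREBF1, a transcription factor gene of lipid synthesis (ENSG00000072310; chromosome 17, 17810399 to 17837002), fell from 29.6 ± 1.55 to 12.03 ± 0.637 RPKM, and SCD, the stearoyl-CoA desaturase, from 92.4 ± 0.846 to 45.4 ± 0.609 RPKM (SD, n = 3). SAT1, which acetylates polyamines for their breakdown, was 2.03-fold lower and fell from 933 ± 18.1 to 459.6 ± 8.53 RPKM. DDIT4, an inhibitor of mTORC1, was 2.11-fold lower, and 847 of its exon bases overlap DDIT4-AS1 on the opposite strand. METTL7A was 2.46-fold lower, NREP 2.35-fold, the microtubule-associated protein gene MAP2 2.26-fold, RENBP 2.19-fold, QPRT of NAD synthesis 2.00-fold and the protease gene ADAMTS1 1.93-fold. ENSG00000263463, an identifier without a name in GENCODE 29, was 3.33-fold lower on only 12.3 against 3.67 reads per sample.

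**Figure D2:**
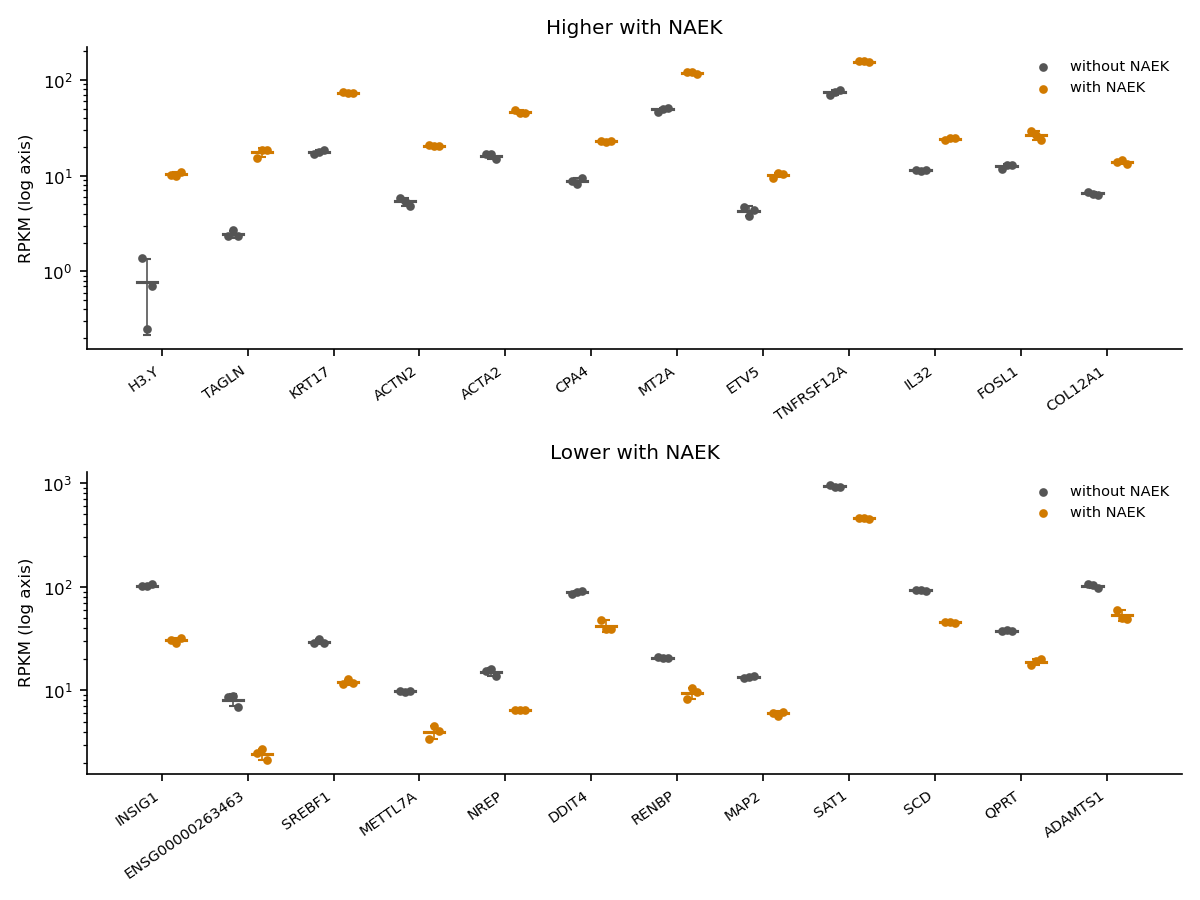
RPKM on a log axis of the 12 genes with the largest rise (top) and the largest fall (bottom), 3 samples without NAEK (grey) and 3 with NAEK (orange), with points for samples, horizontal bars for means and error bars for SDs. The groups do not overlap for any of these genes, and H3.Y without NAEK has the widest relative spread, 0.775 ± 0.561 RPKM.

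Most cholesterol synthesis genes fell: 18 of 24 fell and 1 rose (20 and 1 adjusted over the list alone; camera adjusted p = 1.67e-10, adjusted p = 0.109 with an estimated correlation). Besides INSIG1, IDI1 was 1.79-fold, HMGCS1 1.62-fold and SQLE 1.30-fold lower. These 3 encode enzymes of the mevalonate and sterol pathway. In the list of NRF2 oxidative stress targets 9 of 18 fell and 2 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.00403, adjusted p = 0.233 with an estimated correlation). The members that moved most included the iron storage genes FTH1 (1.38-fold lower) and FTL (1.26-fold lower) and the haem oxygenase gene HMOX1 (1.45-fold lower), while the autophagy receptor gene SQSTM1 rose 1.28-fold.

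Many mRNAs of the ribosome and of oxidative phosphorylation fell, by small amounts. Of 78 cytosolic ribosomal protein genes 55 fell and 0 rose (59 and 0 adjusted over the list alone; camera adjusted p = 6.69e-14, adjusted p = 0.304 with an estimated correlation). Their median log2 fold change was -0.13, with RPL37A 1.32-fold, RPL12 1.28-fold and RPSA 1.18-fold lower. Of 40 nuclear-encoded oxidative phosphorylation genes 23 fell and 1 rose (25 and 2 adjusted over the list alone; camera adjusted p = 8.1e-07, adjusted p = 0.260 with an estimated correlation). COX7C was 1.251-fold and NDUFV1 1.26-fold lower. Of 13 mRNAs encoded by the mitochondrial genome, 4 rose, 0 fell and 9 did not pass, with MT-CO1 at -0.07 and MT-ATP6 at -0.02. The counts were the same adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.523 with an estimated correlation). MT-ND3 rose 1.28-fold, MT-ND2 1.245-fold and MT-ND1 1.24-fold. Without the second sample with NAEK the list's camera adjusted p was 0.0650, and over the alternatives it ranged from 1.89e-05 to 0.523. MT-ND1 did not pass without any of the 3 samples without NAEK or without the third with it, at adjusted p of 0.0812 to 0.0937, nor with limma-voom (0.0613; 1.28e-04 to 0.0937 over the alternatives).

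Most tested members of 2 chaperone lists rose. In the list of the endoplasmic reticulum unfolded protein response 20 of 28 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 1.77e-07, adjusted p = 0.109 with an estimated correlation). The chaperone genes HSPA5, HYOU1 and HSP90B1 rose 1.247-fold, 1.195-fold and 1.22-fold. Of 22 cytosolic heat shock genes 13 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 6.98e-04, adjusted p = 0.160 with an estimated correlation). CHORDC1, an HSP90 cochaperone gene, rose 1.61-fold, HSPH1 1.42-fold, DNAJA1 1.34-fold and HSP90AA1 1.29-fold. The 3 members that fell were the chaperone genes HSPA1A and HSPB1 and the HSP90 cochaperone gene AHSA1, at log2 fold changes of -0.27, -0.26 and -0.27. HSPA1A did not pass without the second sample without NAEK, at adjusted p = 0.0608 (0.00429 to 0.0608 over the alternatives). DDIT3, a stress-induced transcription factor gene, stood at 31.0 ± 2.15 against 27.2 ± 2.79 RPKM (SD, n = 3) and did not pass (limma adjusted p = 0.0824). Without the first sample without NAEK DDIT3 did pass, at limma adjusted p = 0.0111. It also passed with the replicate number as a block and with limma-voom, and over the alternatives its adjusted p ranged from 0.0111 to 0.225.

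The list of ATF4 and amino acid response genes moved both ways: 9 of 35 rose and 14 fell (10 and 16 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0770, adjusted p = 0.506 with an estimated correlation). It passed without the first sample with NAEK (camera adjusted p = 0.0396) and without the level filter (0.0198), with camera values from 0.0198 to 0.506 over the alternatives. ASNS, asparagine synthetase, was 1.71-fold lower, at 55.8 ± 2.59 against 95.3 ± 3.38 RPKM (SD, n = 3), and PHGDH of serine synthesis was 1.90-fold lower. SLC7A5 and SLC3A2, the 2 subunits of a transporter of large neutral amino acids, rose 1.34-fold and 1.36-fold. Of 23 amino acid transporter genes 9 rose and 10 fell (11 and 10 adjusted over the list alone), with SLC7A1, a transporter of cationic amino acids, 1.27-fold and SLC1A4 1.51-fold higher. This list had a negative median (-0.056) and a test in the positive direction (camera adjusted p = 0.733, adjusted p = 0.829 with an estimated correlation). Of 23 aminoacyl-tRNA synthetase genes 4 rose and 6 fell (6 and 7 adjusted over the list alone), with QARS 1.27-fold lower and AIMP2 1.21-fold higher, and its median and test also differed in sign (median 0.010, camera adjusted p = 0.825). The test of this list turned positive without the third sample of either group. Of 10 lysine catabolism genes 2 rose and 4 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.0679), with ECHS1 1.19-fold lower and HADH 1.14-fold higher. This list passed with quantile normalization (camera adjusted p = 0.0411) and without the level filter (0.00755), with camera values from 0.00755 to 0.243 over the alternatives.

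Genes of translation termination and mRNA surveillance were of prior interest because of amber codons. Of 18 nonsense-mediated decay factor genes 14 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 2.97e-05, adjusted p = 0.109 with an estimated correlation). UPF1, the helicase of the pathway, rose from 117 ± 0.941 to 150.8 ± 2.26 RPKM (SD, n = 3) and SMG5 1.203-fold. Of 31 known substrates of this decay 19 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 2.57e-07, adjusted p = 0.109 with an estimated correlation). The splicing factor gene SRSF6 rose 1.42-fold, the noncoding SNHG15 1.38-fold and the stress gene GADD45A 1.48-fold. Several decay factors, UPF1 among them, stand in both lists. Of 22 genes of termination and ribosome quality control 9 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0141, adjusted p = 0.134 with an estimated correlation). ASCC3 and ASCC2, of the complex that splits stalled ribosomes, rose 1.47-fold and 1.16-fold, and TCF25 was 1.32-fold lower. ETF1, the release factor that reads all 3 stop codons, was at 144 ± 2.82 against 140.4 ± 2.96 RPKM and did not pass (limma adjusted p = 0.292).

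Genes whose own stop codon is TAG were compared with the other protein-coding genes. Of the 1166 tested genes in which every annotated coding transcript ends in TAG, 274 rose and 254 fell, with a median log2 fold change of 0.019. Genes ending only in TAA (1596) and only in TGA (3656) had medians of 0.0041 and 0.0043. The TAG class exceeded the 11253 other genes by a median of 0.019, which camera with its preset correlation did not separate from 0 (p = 0.716). The other genes include 6001 whose coding transcripts end in different stop codons, in part TAG. Transcripts annotated for nonsense-mediated decay were counted as coding. Some of the 6001 may therefore differ only by such a transcript, and TAG may be the stop codon of their other transcripts. With genes that have any transcript ending in TAG as the class, the difference turned to -0.0023 (p = 0.749 with the preset correlation).

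Of 27 p53 target genes 21 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 3.45e-08, adjusted p = 0.109 with an estimated correlation). MDM2, which ubiquitinates p53, rose 1.40-fold, the nuclease gene AEN 1.48-fold, the BH3-only gene PMAIP1 1.43-fold and the death receptor gene FAS 1.61-fold. Of 14 NF-kB and inflammatory genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 6.5e-04, adjusted p = 0.134 with an estimated correlation). The NF-kB subunit genes RELB and NFKB2 rose 1.90-fold and 1.55-fold, and the chemokine gene CCL2 was 1.81-fold lower. Of 20 immediate early genes 8 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.00152, adjusted p = 0.504 with an estimated correlation). CTGF, FOSL1 and DUSP5 rose 1.74-fold, 2.09-fold and 1.70-fold, and MYC was 1.44-fold lower. Interferon-stimulated genes did not pass as a list (camera adjusted p = 0.0981): 10 of 26 rose, OAS3 and IRF7 among them (1.72-fold and 1.604-fold), and 5 fell, among them BST2 (1.67-fold lower) and IFITM1 (1.42-fold lower). Adjusted over the list alone these counts were 11 and 5. The interferon list passed without the level filter (camera adjusted p = 0.00295, from 0.00295 to 0.243 over the alternatives).

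Among genes of proliferation, 2 lists passed with small changes. Of 32 genes of DNA replication and G1/S 16 rose and 5 fell (camera adjusted p = 0.0068, adjusted p = 0.134 with an estimated correlation), with CDC6 1.18-fold and TYMS 1.12-fold higher. Of 31 genes of G2/M and mitosis 11 rose and 1 fell (camera adjusted p = 0.0068, adjusted p = 0.407 with an estimated correlation), with HMMR 1.196-fold and ANLN 1.13-fold higher. In both lists the counts were the same adjusted over the list alone. Of 12 histone genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 3.19e-04, adjusted p = 0.109 with an estimated correlation), among them the linker histone gene H1F0 (1.29-fold) and HIST1H2BK (1.48-fold).

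**Figure D3:**
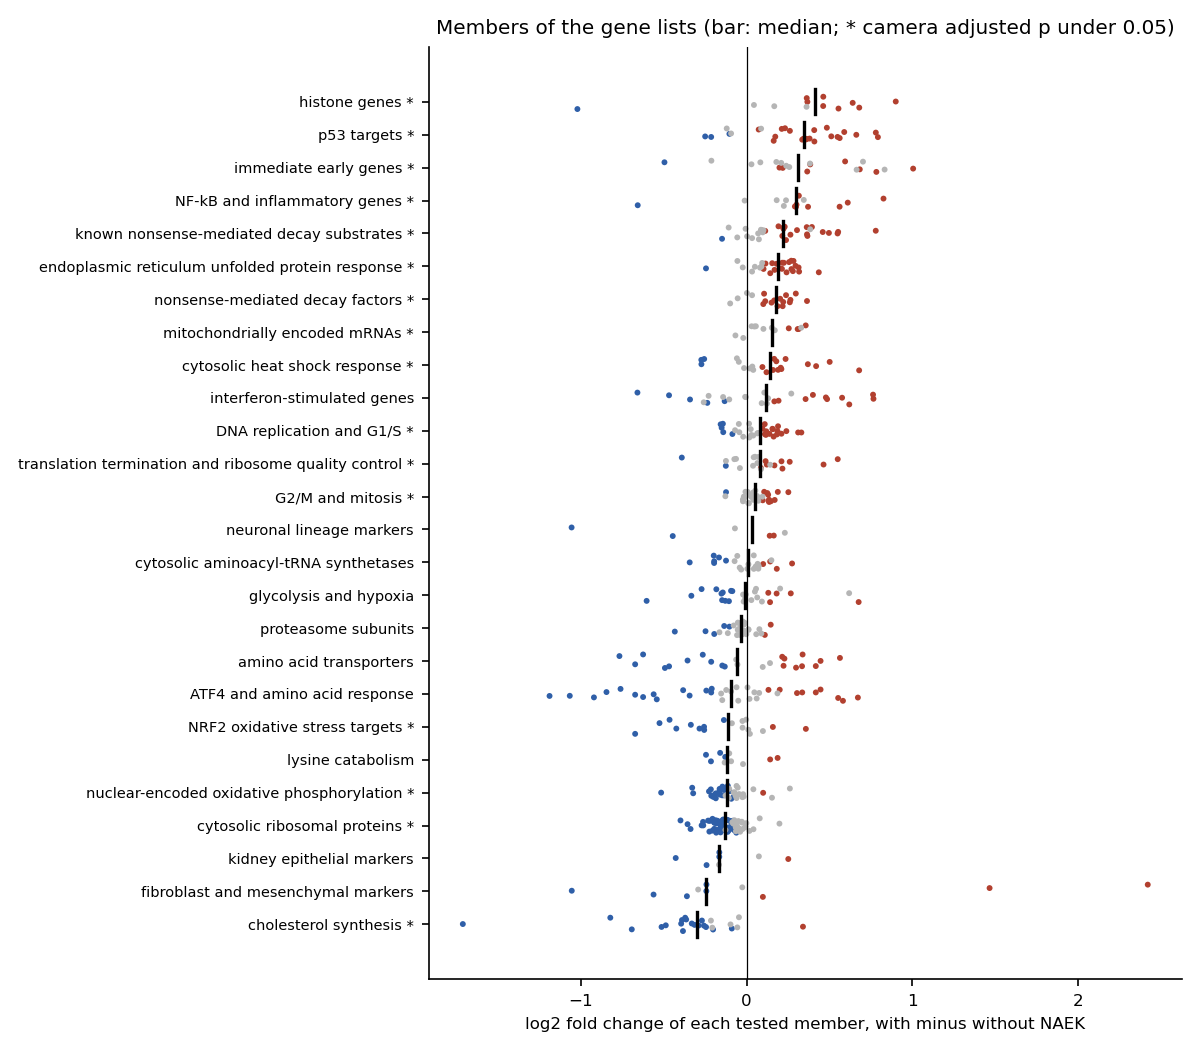
Log2 fold change of each tested member of the 26 gene lists with at least 5 tested members, ordered by list median (black bar), with red members that rose, blue members that fell and grey members that did not pass limma adjusted p 0.05. An asterisk marks the 16 lists that passed with camera at its preset correlation of 0.01, of which 0 passed with an estimated correlation.

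Lists that did not pass included energy metabolism, protein breakdown and markers of cell types. Of 27 glycolysis and hypoxia genes 5 rose and 11 fell (camera adjusted p = 0.502), with GPI 1.21-fold lower and SLC2A1 1.14-fold higher. The median (-0.0093) and the mean (0.0072) of this list differed in sign. Of 31 proteasome genes 2 rose and 5 fell (camera adjusted p = 0.0679), with PSMC3 1.35-fold lower and PSMD12 1.11-fold higher. The proteasome list passed without the first or the second sample without NAEK (camera adjusted p = 0.0250 and 0.0308), with the replicate number as a block (0.0463), with quantile normalization (0.0404) and without the level filter (0.0143), with values from 0.0143 to 0.585 over the alternatives. Adjusted over the list alone the counts were 6 and 11 for glycolysis and 2 and 5 for the proteasome. Of 10 fibroblast and mesenchymal markers 3 rose and 5 fell (camera adjusted p = 0.266). TAGLN and ACTA2 rose, while the matrix genes LUM and COL1A1 were 2.85-fold and 1.497-fold lower, and the mean of the list (0.12) was positive with a median of -0.24. This list passed without the level filter (camera adjusted p = 0.0382, from 0.0382 to 0.534 over the alternatives). Of 7 kidney epithelial markers 1 rose and 4 fell (camera adjusted p = 0.0671), with the keratin genes KRT8 and KRT18 both 1.12-fold lower. The kidney list passed with limma-voom (camera adjusted p = 0.0356) and without the level filter (0.0345), with values from 0.0345 to 0.304 over the alternatives. Of 6 neuronal markers 2 rose and 2 fell (camera adjusted p = 0.797, with a test in the negative direction, positive without the level filter, and a median of 0.034). MAP2 and GAP43 were 2.26-fold and 1.67-fold lower, and NEFL rose 1.103-fold, a call that was lost without the first sample without NAEK (adjusted p = 0.0507, from 0.00124 to 0.0507 over the alternatives). Adjusted over the list alone, 3 and 5, 1 and 5, and 3 and 2 members of these 3 marker lists rose and fell. Endothelial and erythroid markers had 1 tested member, VWF, which did not pass (limma adjusted p = 0.533).

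The first principal component of the tested genes held 55.6% of the variance and separated the 2 groups. The first sample with NAEK stood apart from the other 2 of its group on the second component, which held 13.4%. Its chi-square per gene against them was 3.32 and 3.01, against 1.6 between those 2. Chi-square per gene was 1.45 to 2.07 among the samples without NAEK and 11.4 to 15.4 between groups. Without that sample 4944 genes passed. Exon bases shared with a gene on the opposite strand made up 62.4% of FTH1, 41.2% of DDIT4, 39.1% of TYMS, 28.9% of AIMP2, 27.2% of DDIT3 and 20.7% of SQSTM1. AC079781.5, which is not in the table, shares 44.6% of ASNS on the same strand, and IFITM2 32.5% of IFITM1.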

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

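The tests of GC content and length and of the DUX4 target list, and the use of median scaling, itself an alternative planned before, as a test of scaling, were chosen only after the results had been seen; the tests of other splits, of variation between samples and of matched lists were chosen before.

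Below the level filter, 19209 genes had reads, and without the filter 216 of them passed limma adjusted p 0.05, 104 higher and 112 lower with NAEK. The 13 given here were picked as higher: they averaged at least 10 reads per sample with NAEK, at least 4 times the mean without it, with groups that did not overlap. The mirrored rule, applied after these had been seen, gave 5 genes lower with NAEK: PLXNA4 (8.33 reads against 40.3), AC239800.2 (4.33 against 19), CHRNA9 (4.33 against 17.7), PTGIR (3 against 13.3) and WNT8B (2.33 against 13.3). ACTL8, an actin-like gene, had 32 ± 13 reads per sample with NAEK and 8 ± 2.65 without (SD, n = 3). The TRIM family genes TRIM49C, TRIM48, TRIM49B, TRIM43B, TRIM64B and TRIM43 averaged 27.3, 22.7, 21.3, 21, 16 and 15.3 reads with NAEK, against 3, 3.33, 3.67, 1.67, 3 and 2.67 without. The TRIM pseudogenes TRIM53AP, TRIM51BP and TRIM53CP averaged 22.3, 15 and 13 reads with NAEK, against 3.33, 3 and 1.67 without. AC126177.6 averaged 17 reads against 2.33, SSU72P8 14.7 against 0.667, and the noncoding AC024884.2 13.3 against 3.33. For the 13, adjusted p without the filter lay between 0.0025 for AC126177.6 and 0.0457 for TRIM64B. Many of the 13 are near-identical copies, so which copy gave the reads is uncertain.

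Several of these genes, with H3.Y, are known targets of DUX4, a transcription factor of the early embryo. Of 35 genes on a list of its targets 20 had 10 reads or more, and 15 of these were at least 2-fold higher with groups that did not overlap. Of the 15, 10 belong to the families whose rise prompted the list. Of the 10 other members 5 (50%) were higher in this way, against 3.01% of 11992 genes in the list's range of reads. The top of that range was set by CCNA1 (517 reads with NAEK and 310 without), while the 5 had 17 to 66 reads with NAEK. Counting error opens such gaps more often at low reads, so 3.01% may be too low a rate for them. Of these 5 only SLC34A2 passed without the filter (limma adjusted p = 0.0209), and ZSCAN4, PRAMEF1, PRAMEF12 and KDM4E did not (0.0508 to 0.160). Deeper libraries are argued against by a ratio of library totals of 0.986. By the measure of fold and overlap 7 families held a higher member, but 3 of them prompted the list. Without these 3 families 4 of 6 (66.7%) held a higher member, but only 1 of the 4, SLC34A, held one that passed. CCNA1, 1.69-fold higher, missed the 2-fold measure but passed without the filter (limma adjusted p = 0.00353). PRAMEF2, RFPL2, RFPL4A and RFPL4B neither met the measure nor passed. With so few reads, reads shared between paralogs cannot be told apart from higher activity of DUX4. DUX4 itself had 2 reads with NAEK and 3 without, and its pseudogene copy DUX4L9 had 7 with and 17 without, so these reads show no rise of DUX4 mRNA, and a change in it was not detectable at this depth.

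For the 5746 genes past the threshold, removing each sample's trend on GC content and transcript length kept 96.3% of those testable, and median scaling kept 96.7%, in the same direction, which argues against either as the whole cause. Samples of a group varied by a coefficient of 1.94% beyond counting noise, so 3 samples of a group taken from 1 culture cannot be told apart from 3 similar cultures, since the labels do not say. The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. Only the real split, 1 of the 10, gave as many genes as 5746, and the highest other gave 0. For gene lists the real split called 16, as 1 of 10, and the others called 7 to 11 while calling 0 genes. Camera with its preset correlation thus called lists under every grouping of the samples. Every other split mixes samples of both groups on each side. It thus keeps part of the difference between the groups and adds the rest to the spread. Where the groups differ, the real split is therefore likely to rank first, so its rank alone decides nothing.

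For genes ending in TAG the real difference of medians was 0.019, as 1 of 10 splits, and the highest other 0.0076, with splits again too few for a share under 0.05. The other splits again mix the groups, so this rank does not show that the difference stands out. Camera with its preset correlation did not separate it from 0 (p = 0.716).

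Ribosomal protein and oxidative phosphorylation mRNAs were lower with NAEK by small amounts, with list medians of -0.13 and -0.12. After the trends on GC content and length were removed the medians were -0.12 and -0.10, which argues against these trends as the whole cause. Among 10000 random lists matched on expression and length, the ribosomal median stood at percentile 0 and the oxidative phosphorylation median at percentile 0.07, with matched medians of -0.02 and -0.03. The genes of each list are correlated, and neither list passed with an estimated correlation. A difference in growth between the cultures was not tested.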

How the results depend on the processing

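The alternatives with limma-voom on recovered reads and with GC content and length trends removed were chosen only after the results had been seen.

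Requiring an absolute log2 fold change of at least 1 as well left 56 genes, 30 higher and 26 lower, and an adjusted p of 0.01 left 3487, 1754 higher and 1733 lower, as stricter thresholds must. With an estimated correlation 0 gene lists passed, against 16, with a lowest adjusted p = 0.109. Camera then also takes its degrees of freedom from the 6 samples and not from the number of genes. For the list of termination and ribosome quality control the estimate was -0.0013, below the preset 0.01. Its camera adjusted p still went from 0.0141 to 0.134, so the loss of lists is not all due to correlated genes. The rotation test fry, which asks whether a list changed at all and not, as camera does, whether it changed more than other genes, called 19. With any TAG-ending transcript as the class, the stop codon difference turned to -0.0023. That class holds 4981 genes instead of 1166. The added genes are among those whose transcripts end in different stop codons, which had a median of -0.0028. Leaving out 1 sample at a time gave 4626 to 4944 genes, 2339 to 2464 higher and 2265 to 2531 lower, 15 to 17 lists, and a stop codon difference of 0.012 to 0.016.

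With the replicate number as a block 5631 genes passed, 2808 higher and 2823 lower, and 5323 of the 5746 were shared. Deviations of samples with the same number correlated across genes at 0.037, 0.084 and 0.045, and those with different numbers at -0.075 to 0.027. Each sample correlated best with its own number, a hint from the data, not the design; as no correlation was over 0.1, the numbers were not taken to pair the samples.

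The other alternatives gave 4310 genes (no filter) to 6505 (limma-voom), and 5 of the 5746 genes were opposite, all with quantile normalization. Of 128 genes run singly 123 were past the threshold, of which 117 kept direction and threshold in every alternative run for them, and 0 reversed. MT-ND1, NEFL, HSPA1A, MT-ND4L, LRP2 and NCAM1 lost it in some, and DDIT3, which had not passed, passed in 3. Without 1 sample MT-ND4L had adjusted p = 0.0636 (sample 3 without NAEK), LRP2 0.0518 (sample 3 with it) and NCAM1 0.0525 to 0.0821 (each sample but sample 1 without it), against ranges of 3.99e-05 to 0.108, 1.2e-05 to 0.0518 and 0.0116 to 0.0821 over the alternatives. MT-ATP6, which had not passed, went from -0.056 to 0.0073 without 1 sample and to 0.071 with quantile normalization. By the different question of fry, the immediate early list (adjusted p = 0.0665, from 7.23e-05 to 0.504 over the alternatives) and the mitochondrially encoded list (0.0962, from 1.89e-05 to 0.523) did not pass, and the ATF4, lysine catabolism, interferon, kidney and neuronal lists did, so these are not losses or gains of the camera result. Without the level filter the ATF4, lysine catabolism, interferon, kidney, proteasome and fibroblast lists passed as well; the cause was not tested. The alternatives that need deposited counts (size factors, upper quartile scaling, a count-model Wald test) were not run, since the values are RPKM.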

Other observations

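The genes in this part were chosen after their values had been seen, and the test of ERK targets was chosen only after results had been seen; so was the run without SRF and CYR61, while the other tests of SRF and YAP targets and of decay transcripts were chosen before theirs were.

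Several single genes of fatty acid metabolism were lower with NAEK; no list of them was tested. FADS2 and FADS1, fatty acid desaturases, were 1.68-fold and 1.32-fold lower, the elongase gene ELOVL6 1.39-fold and ACLY 1.09-fold. FASN was 1.11-fold lower but did not pass without the level filter, with plain limma or with GC and length trends removed (adjusted p up to 0.0961), and ACACA and ACSS2 did not pass (limma adjusted p = 0.0788 and 0.431). Tubulin genes moved both ways: TUBA1A, TUBB2B, TUBB4A and TUBB were 1.42-fold, 1.49-fold, 1.46-fold and 1.24-fold lower. TUBA4A and TUBB2A were 1.435-fold and 1.096-fold higher, and TUBA4A did not pass without the first sample of either group (adjusted p up to 0.0628). TUBB4B, 1.07-fold lower (limma adjusted p = 0.0492), did not pass in 11 alternatives (adjusted p up to 0.207), and TUBB6 did not pass (limma adjusted p = 0.889). TUBA1B, 1.12-fold lower, did not pass with quantile normalization, and TUBA1C, 1.08-fold higher, did not pass in 4 alternatives, among them without the first or the second sample without NAEK (adjusted p up to 0.0869). Exon bases shared with a gene on the opposite strand made up 36.6% of TUBA1B.

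In polyamine metabolism ODC1 and SRM, of synthesis, were 1.33-fold and 1.28-fold higher, SMS and AMD1, also of synthesis, did not pass (limma adjusted p = 0.70 and 0.277), and SAT1 and the antizyme gene OAZ2 were 2.03-fold and 1.16-fold lower. The metallothionein gene MT1F was 2.95-fold higher beside MT2A, and MT1X was at 1.13 ± 0.256 RPKM with NAEK against 1.68 ± 0.319 without and did not pass (limma adjusted p = 0.0877). SLC30A1, a zinc exporter, was 1.36-fold higher. The iron uptake genes TFRC and SLC11A2 were 1.345-fold and 1.39-fold lower. The tRNA methyltransferase genes METTL1 and TRMT61A were 1.76-fold and 2.06-fold higher.

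The rise of TAGLN, ACTA2 and CSRP1 (1.93-fold) prompted the hypothesis that SRF or YAP target genes were higher with NAEK. Of 27 tested SRF targets 10 were left out because their values had been seen, among them TPM4, which was lower. Of the 17 others, 11 rose and 0 fell, MYH9, TUFT1 and ZYX among the 11 (camera with its preset correlation, p = 3.25e-05; p = 0.0428 and adjusted p = 0.118 with an estimated correlation). Of 17 YAP targets left after the same step, 7 rose, IGFBP3 and CRIM1 among them, and 2 fell, AXL and CCDC80 (camera with its preset correlation, p = 0.0308; p = 0.171 with an estimated correlation). Without SRF and CYR61, which also stand in the immediate early list tested before, the values were p = 7.26e-05 for 16 SRF targets and p = 0.0496 for 16 YAP targets with the preset correlation, and p = 0.0461 and p = 0.238 with an estimated correlation. The contractile genes VCL, FLNA and TPM2 did not pass (limma adjusted p = 0.837, 0.416 and 0.999). TPM4 passed as lower, at a log2 fold change of -0.09 (limma adjusted p = 0.0258). It did not pass in 6 alternatives, among them without the first or the third sample without NAEK or the first with it (adjusted p up to 0.112). Higher SRF activity may underlie the rise of some contractile genes, but neither list passed adjusted with an estimated correlation.

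ETV4 (3.42-fold), ETV5 and SPRY4 (3.04-fold), known outputs of ERK signalling, were higher with NAEK. Of the 7 remaining ERK pathway target genes 5 rose, DUSP4, DUSP6, EPHA2, CCND1 and SPRY2 (camera with its preset correlation, p = 2.8e-04; p = 0.0786 with an estimated correlation). Most of these values had been seen before the list was tested, so the test could hardly have come out otherwise.

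The list of known decay substrates passed with the preset correlation but not with an estimated one (adjusted p = 0.109), and the 5377 protein-coding genes with an annotated decay transcript had a median log2 fold change of -0.00018, against 0.0026 for 7052 without. A hypothesis was that amber suppression of premature stop codons would raise genes whose decay transcripts end in TAG. The 578 genes whose annotated decay transcripts all end in TAG differed by 0.0059 in median log2 fold change from 3746 genes with none (camera with its preset correlation, p = 0.734), which decides neither way. The values are per gene, so single decay transcripts were not measured.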
